A study of Homo sapiens with 8 samples.

How the data were processed

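DNA from RPE1 cells, an hTERT-immortalised line of human retinal pigment epithelial origin, was profiled by OGAP-seq, a sequencing method in which fragments carrying oxidative base damage are pulled down before library preparation. Cells were compared without (WT) and with depletion (KD) of NuMA, a large nuclear and spindle-pole protein that the labels also call TDIF. For each state there were 2 OGAP libraries and 2 input libraries of DNA that was not pulled down, 8 libraries in all. Per the labels' protocols, the KD cells are the post-doxycycline cells and the WT cells had no doxycycline, so that doxycycline and depletion cannot be told apart in any comparison. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

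The deposited counts are whole numbers of reads per promoter window, in a table that the authors made for 19957 Ensembl genes and all 8 libraries. Per the submitters' processing notes, the tools used were BWA 0.7.17-r1188, bedtools, featureCounts and MACS2, and the build was hg38. The other deposited files hold coverage signal summed over genes by the authors, per library, at 6000 positions around gene starts and 6000 around gene ends, and in 1000 bins each upstream of, over the exons of and downstream of genes. The scale of these sums and the spacing of the positions are not given in the sources used here. The sums followed library depth, so that coverage was compared only after division by the mean of the same library's outer positions. This replaced the plain central mean written in the design before the data were examined. No column of per-sample values was left out.

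Each window spanned 2001 bp centred on an annotated gene start. The table carried Ensembl identifiers without symbols, and the RefSeq table used here (GRCh38.p14) held no Ensembl identifier. Windows were therefore named by position, where the centre lay within 500 bp of the start of exactly 1 protein-coding gene on the same strand. This named 15130 windows (75.8%), against 1.55% after all windows were shifted by 200 kb. Of all windows, 3741 (18.8%) overlapped another window; these held far fewer reads than the rest, and their values are uncertain because reads shared by a pair of windows seem to have been left uncounted. The 452 windows without a read in any library were not tested.

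Total promoter reads were 368593 and 397173 in WT OGAP, 727901 and 771138 in WT input, 560174 and 449833 in KD OGAP, and 683567 and 645276 in KD input. The median window held 17 and 18 reads in WT OGAP, 28 and 22 in KD OGAP, and 33 to 38 in the inputs. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom of 1.91 in WT OGAP, 2.14 in WT input, 2.06 in KD OGAP and 1.97 in KD input, so that no pair was treated as a single library; this does not show that they came from separate cultures.

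Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and test, TMM scaling, filterByExpr), in a model with 4 group means over all 8 libraries. The filter kept 17130 windows. Comparisons were OGAP over input in WT, the same in KD, KD against WT in OGAP, KD against WT in input, and the interaction, which is the KD effect on OGAP over input. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. An adjusted p for a window comes from this edgeR test unless another test or setting is named with it. Log2 fold changes are given ± SE. The SE was back-calculated as the absolute log2 change over the square root of the F value of the test, so it is approximate. The common biological coefficient of variation was 0.178. The spread of each window was drawn strongly toward that of all windows, with 98.4 prior against 4 residual degrees of freedom. The p and SE of a window therefore say little about how closely its own libraries agreed. Gene lists fixed before the data were examined were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the 23 lists of a comparison. The alternatives used an estimated correlation, and fry. List counts are of tested windows, and the count filter removed members of some lists. It kept 15 of 27 named windows for base excision and single-strand break repair and 14 of 22 for double-strand break repair. For oxidative phosphorylation it kept 43 of 64.

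Simulated counts had 200 changed windows among 17130, all drawn from windows at or above the median abundance. On these counts the test of OGAP over input in WT recovered 23.9% of the 2-fold changes and 90.9% of the 4-fold changes. For KD against WT in OGAP the shares were 28.4% and 86.4%. For the interaction they were 6.0% and 50.0%. Windows below the median abundance were not among the changed ones, so the shares do not describe them. The adjusted threshold also depends on how many windows change, and each simulation changed 200. The data gave 2346 calls in WT, 6 for KD against WT in OGAP and 1 for the interaction. The shares are therefore not recovery rates of these data, and are likely too low for WT and too high for the interaction. A missing call in the interaction therefore says little about changes of 4-fold or less.

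Windows named in the text followed a rule set before the data were examined. For each comparison other than OGAP over input in KD, these were the 10 windows with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold. Their libraries had to be without overlap between the groups and their mean log2 CPM at or above the median, and only symbols of named protein-coding genes counted, with names ending in P plus digits left out. Open places went to the lowest unadjusted p and are said not to have passed. OGAP over input in KD was described at the genes named for WT. NUMA1 was always named, and so were up to 4 members of each list with the lowest p. USP11 and AKIRIN1 lay outside the rule and were chosen after their values were seen, as were the windows without a name.

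Group ratios of coverage and chromosome shares of reads are means ± SD over libraries, compared with two-sided exact permutation tests; 2 against 2 libraries cannot go below p = 0.33, and 4 against 4 cannot go below 0.0286. To compare OGAP over input between WT and KD without selection on noise, covariances between independent library pairs gave a noise-corrected slope of KD on WT across windows (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). On simulated counts with a slope of 0.5 over 8594 windows this recovered 0.505. Alternatives covered scaling, DESeq2 1.42.0, count filters, replicate blocks, chromosomes, overlapping windows, and each library left out. No genome sequence was used here, so that no GC correction was made.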

Results

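The labels state the purpose of the series as measuring how depletion of NuMA changes oxidative damage across the genome. OGAP-seq was run on RPE1 cells in 4 groups of 2 libraries: WT OGAP, WT input, KD OGAP and KD input. The 8 libraries held 368593 to 771138 reads in promoter windows. Across the 17130 tested windows, log2 CPM correlated between replicates at r = 0.65 in WT OGAP, 0.61 in KD OGAP, 0.77 in WT input and 0.72 in KD input. Over windows in the upper part by mean count, a setting chosen after seeing the data, these were 0.574, 0.326, 0.474 and 0.347. The first KD OGAP library correlated with the 4 inputs at 0.59 to 0.61 and the second at 0.47 to 0.50, where the WT OGAP libraries did so at 0.35 to 0.43. These correlations are across windows, which are not independent replicates.

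The targeted gene was looked at first. The NUMA1 window (Ensembl ENSG00000137497, hg38 chromosome 11, 72079694 to 72081694, minus strand) held 6 and 5 reads in WT OGAP, 2 and 1 in WT input, 11 and 4 in KD OGAP, and 8 and 16 in KD input. NUMA1 passed the threshold in none of the comparisons. Its log2 change between KD and WT was 3.03 ± 0.97 in input (adjusted p = 0.999, edgeR) and -0.03 ± 0.85 in OGAP (adjusted p = 0.994). The window overlaps a neighbouring window and counts DNA, so it checks nothing about the depletion.

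Around gene starts, OGAP coverage dipped in WT while input coverage rose in both states. The WT OGAP ratio of the central 1000 positions to the outer positions was 0.851 ± 0.014 (SD, n = 2), against 1.22 ± 0.08 in WT input. In KD OGAP the ratio was 0.971 ± 0.053, against 1.15 ± 0.03 in KD input. All 4 OGAP libraries lay below all 4 input libraries at gene starts (exact permutation p = 0.0286, two-sided, the smallest possible with 4 against 4). The deepest point of the WT OGAP profile lay 88 and 94 positions downstream of the start, at 0.776 and 0.745 of the outer level.

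Gene ends and exons had the same order of groups. At gene ends the ratio was 0.877 ± 0.005 in WT OGAP and 0.945 ± 0.023 in KD OGAP, against 1.019 ± 0.008 and 1.01 ± 0.002 in the inputs of WT and KD. Over exons it was 0.844 ± 0.005 in WT OGAP and 0.958 ± 0.051 in KD OGAP, against 1.14 ± 0.04 and 1.09 ± 0.01 in the inputs. In both regions the 4 OGAP libraries lay below the 4 inputs (exact permutation p = 0.0286 each, over 3 regions). KD OGAP exceeded WT OGAP by 0.119 at gene starts, 0.068 at gene ends and 0.113 over exons, without overlap of the libraries. The inputs of WT and KD separated too, in the opposite direction. KD minus WT in input was -0.077 at gene starts, -0.009 at gene ends and -0.044 over exons, likewise without overlap of the libraries. With 2 against 2 libraries the exact permutation p was 0.33 in each region for OGAP and for input, the smallest this design allows.

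**Figure D1:**
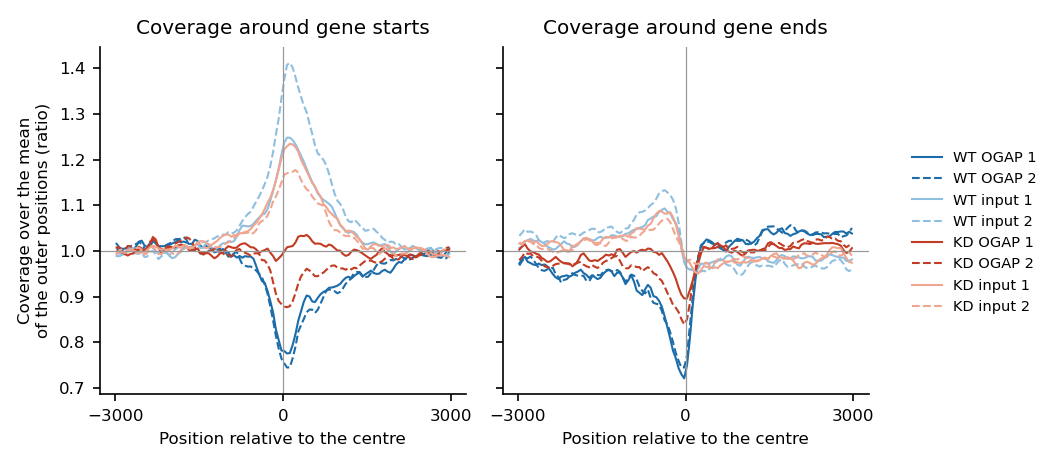
Coverage around gene starts (left) and gene ends (right), divided by the mean of each library's own outer positions, against position from the centre; each line is 1 library, solid for replicate 1 and dashed for replicate 2. WT OGAP fell to 0.776 and 0.745 near gene starts, KD OGAP stayed closer to 1, and the 4 inputs peaked above it.

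OGAP over input in WT asked which promoters were over- or under-represented, relative to other promoters, in the pull-down of unperturbed cells. USP11, a deubiquitinase gene on chromosome X, and EXOC8, which encodes an exocyst subunit, had the lowest p-values, with log2 changes of 5.23 ± 0.22 and 5.78 ± 0.27. USP11 (47231689 to 47233689, plus strand) held 1338 and 1052 reads in WT OGAP against 77 and 55 in WT input. EXOC8 (chromosome 1, 231336853 to 231338853, minus strand) held 832 and 694 against 42 and 15, in a window that overlaps a neighbouring window. DBF4B, an activator of the replication kinase CDC7, was higher by 2.76 ± 0.26 (adjusted p = 3.54e-14, edgeR), and GSTA4, a glutathione transferase acting on products of lipid peroxidation, by 2.18 ± 0.31 (adjusted p = 2.11e-07). Among windows that the naming rule admits, which needs reads at or above the median, the lower side was led by ATRNL1 at -2.32 ± 0.39, SIX5, a homeobox gene, at -2.16 ± 0.40 and CNNM4, a magnesium transporter gene, at -1.92 ± 0.41.

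In all, 2346 of 17130 windows passed the threshold in WT, 1584 higher and 762 lower (n = 2 libraries per group, edgeR). Higher and lower are relative to the typical promoter window, because only promoter windows were counted and scaled (median log2 change of -0.022). A higher window therefore need not be enriched over the rest of the genome. The other higher windows named by the rule were TEX46 (2.5 ± 0.36), FOLR2 (2.32 ± 0.35), EFCAB9 (2.31 ± 0.35), PIWIL3 (2.25 ± 0.33), ATP5MGL (2.24 ± 0.32), OLAH (2.24 ± 0.35) and the read-through gene MSANTD3-TMEFF1 (2.21 ± 0.36). The other lower windows were TSPAN17 (-1.84 ± 0.36), MYH9, the gene of non-muscle myosin IIA (-1.81 ± 0.36), ZBTB48, a telomere-binding zinc finger gene (-1.81 ± 0.36), FAM20C, a secretory pathway kinase gene (-1.78 ± 0.39), FNDC10 (-1.77 ± 0.42), TMEM200B (-1.75 ± 0.41) and PRXL2B (-1.74 ± 0.39). The count fell to 879 without WT input replicate 2, to 1210 without WT OGAP replicate 2 and to 1505 without WT input replicate 1. It was 884 with the DESeq2 test. Without WT OGAP replicate 1, CNNM4 (-1.32), FNDC10 (-1.35) and TMEM200B (-1.32) did not pass, and without WT input replicate 2, FNDC10 (-1.39) and PRXL2B (-1.11) did not.

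Among the gene lists in WT, immediate early genes, which respond first to growth factors and stress, were lower in OGAP by camera, and nuclear-encoded oxidative phosphorylation genes were higher. Neither list passed with an estimated correlation (adjusted p = 0.209 each). Of 27 immediate early windows tested, 6 were lower and 2 higher past the threshold, and 11 and 2 when adjusted over the list alone. The list median was -0.49 (camera, adjusted p = 0.00559). JUND (-1.64 ± 0.38), JUNB (-1.44 ± 0.36), which are AP-1 transcription factors, and the phosphatase gene DUSP5 (-1.19 ± 0.33) fell, and the nuclear receptor gene NR4A1 rose by 1.07 ± 0.30. Of 43 oxidative phosphorylation windows, 9 were higher and 0 lower, and 10 and 1 when adjusted over the list alone, with a median of 0.40 (camera, adjusted p = 0.0139). Its members included COX6B1 (1.55 ± 0.33) of cytochrome c oxidase and SDHB (1.37 ± 0.30) of succinate dehydrogenase. Without WT OGAP replicate 2 the oxidative phosphorylation list no longer passed, at a median of 0.34.

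Genes of DNA repair and stress responses were mixed in WT, and none of the following lists passed camera. Of 15 windows for base excision and single-strand break repair, 3 were higher, namely PARP1 (1.46 ± 0.29), PARP2 (1.44 ± 0.36) and the DNA glycosylase gene NEIL1 (1.14 ± 0.33); OGG1, the 8-oxoguanine glycosylase gene, was at 0.75 ± 0.30 (adjusted p = 0.0825, edgeR). Camera gave this list an adjusted p of 0.433. Of 14 double-strand break repair windows, 3 were higher, RNF168 (1.29 ± 0.35) among them. Camera gave an adjusted p of 0.413, while the list passed as higher with fry (adjusted p = 0.0263) at a median of -0.03. Of 17 p53 targets, 3 were higher, namely the apoptosis gene BBC3 (1.84 ± 0.29), DDB2 (1.26 ± 0.32) and the cell cycle inhibitor gene CDKN1A (1.12 ± 0.33), with a list median of -0.24 (adjusted p = 0.938). Of 29 NRF2 target and antioxidant windows, 3 were higher, with AKR1B10 at 1.32 ± 0.32 and the peroxiredoxin gene PRDX3 at 1.15 ± 0.29 (list adjusted p = 0.517). Of 10 heat shock and chaperone windows, HSPH1 (-1.37 ± 0.47) and HSP90AB1 (-1.06 ± 0.38) were lower (list adjusted p = 0.493). Among 21 inflammatory and NF-kB windows, 1 was lower, LIF at -1.13 ± 0.37 (list adjusted p = 0.938).

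Lists of the transcription and chromosome machinery gave these counts in WT. Of 22 elongation and pausing windows, 3 were higher and 1 lower, with NELFCD at 1.57 ± 0.33, POLR2D at 1.28 ± 0.33 and the topoisomerase gene TOP1 at -1.32 ± 0.38 (list adjusted p = 0.938). None of 21 core promoter and chromatin regulators passed (list adjusted p = 0.657), nor any of 23 spindle and NuMA partner genes, with PARD3 at -1.24 ± 0.47 and KIF11 at 0.84 ± 0.34 (list adjusted p = 0.433). Of 52 cytoplasmic ribosomal protein windows, 7 were higher and 2 lower (list adjusted p = 0.282), with RPS27 at 1.44 ± 0.36 and RPLP0 at 1.22 ± 0.30. Of 39 histone windows, 2 were higher and 1 lower (list adjusted p = 0.433), but most of its named members overlap neighbouring windows. Of 339 ZNF windows, 43 were higher and 11 lower, with ZNF444 at 1.85 ± 0.29 and ZNF253 at 1.82 ± 0.34 (list adjusted p = 0.282).

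Clustered gene families and markers of cell types and tissues, the retinal pigment epithelium among them, were likewise not past the list threshold by camera in WT. HOX genes had 1 lower of 22 (HOXA11, -1.08 ± 0.39; list adjusted p = 0.185), protocadherins 0 of 49 (0.622), olfactory receptors 12 higher and 1 lower of 168 (0.308), and keratin-associated proteins 3 higher and 1 lower of 88 (0.938). Retinal pigment epithelium markers had 1 higher of 18, SERPINF1 at 1.22 ± 0.30 (list adjusted p = 0.603). Photoreceptor markers had 2 higher of 20, PDE6G at 1.83 ± 0.31 and PRPH2 at 1.01 ± 0.35 (0.657). Neuronal synapse genes had 1 higher, CAMK2A at 1.41 ± 0.31, and 2 lower of 23 (0.282). Immune cell markers had 1 higher of 22 (0.282), and mesenchymal and matrix genes had 1 higher, COL3A1 at 1.64 ± 0.51, and 1 lower of 24 (0.517).

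OGAP over input in KD asked the same of depleted cells. EXOC8, USP11 and DBF4B, the 3 windows with the lowest p in WT, were high again, at 5.96 ± 0.29, 4.74 ± 0.23 and 2.36 ± 0.26. Of the other higher windows named in WT, 3 passed, namely GSTA4 (1.95 ± 0.30, adjusted p = 1.15e-05, edgeR), ATP5MGL (1.55 ± 0.33) and TEX46 (1.36 ± 0.33), and 5 did not: OLAH (1.10 ± 0.34), PIWIL3 (0.92 ± 0.32), EFCAB9 (0.69 ± 0.34), FOLR2 (0.64 ± 0.35) and MSANTD3-TMEFF1 (0.53 ± 0.33). None of the 10 lower windows named in WT passed in KD, where ATRNL1 was at -0.67 ± 0.33, FAM20C at -1.0 ± 0.35, PRXL2B at -0.82 ± 0.35 and CNNM4 at 0.01 ± 0.34.

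In KD 126 windows passed, 108 higher and 18 lower, and none of the 23 gene lists did; the smallest camera adjusted p was 0.135, and 2162 windows had an unadjusted p under 0.05. Of the 108 higher windows, 96 were also higher in WT, where independent lists would share 9.99, and of the 18 lower windows 7 were also lower in WT, against 0.80. The comparisons share no library, but one model gave the spread for both. The counts of 9.99 and 0.80 take every window as equally likely to be called. Calls also depend on the reads of a window, which were not matched, so part of the excess may follow from that. Of the windows higher in WT, 93.2% had a positive log2 change in KD, with medians of 1.34 in WT and 0.62 in KD. Of those lower in WT, 84.0% were negative in KD, with medians of -1.28 and -0.35. The WT medians are inflated because these windows were selected in WT. Among list members, LYZ (1.77 ± 0.40), BBC3 (1.23 ± 0.30) and PDE6G (1.44 ± 0.31) rose, and CDK9, the pause-release kinase gene, fell by 1.59 on the log2 scale (± 0.42). The count fell to 7 without KD input replicate 1, to 9 without KD OGAP replicate 2, to 21 without KD input replicate 2 and to 82 without WT input replicate 2, and was 64 with DESeq2. Without KD OGAP replicate 2, GSTA4 (1.35), ATP5MGL (1.42) and TEX46 (1.3) did not pass, and without KD input replicate 1 neither did GSTA4 (1.64), ATP5MGL (1.42) and TEX46 (0.99); ATP5MGL also needed KD input replicate 2 (1.67 without it) and TEX46 KD OGAP replicate 1 (1.42).

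**Figure D2:**
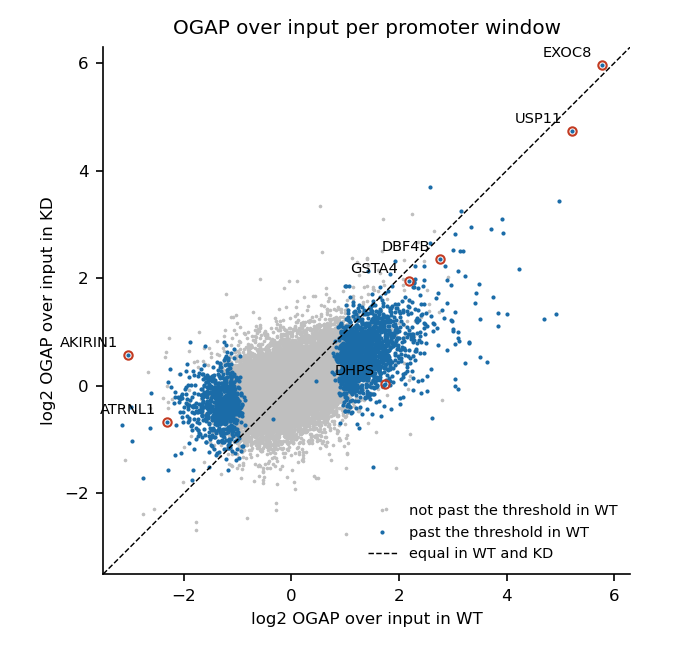
Log2 OGAP over input of each tested promoter window in WT (horizontal) and KD (vertical); blue points passed the threshold in WT, circles mark named windows, and the dashed line marks equal values. EXOC8 and USP11 lie near the line in both states, while AKIRIN1 was at -3.03 in WT and 0.57 in KD; 4 windows lie outside the plotted range.

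KD against WT in OGAP asked which promoters changed their share of the pull-down on NuMA depletion. Of the windows past the threshold, AKIRIN1, which encodes a small nuclear protein, rose from 3 and 2 reads in WT OGAP to 37 and 29 in KD OGAP (3.23 ± 0.59, adjusted p = 0.00509, edgeR), and NCF4, an NADPH oxidase subunit gene, rose by 1.56 ± 0.33 (adjusted p = 0.0262). DHPS, the deoxyhypusine synthase gene, fell by 1.46 on the log2 scale (± 0.29), from 75 and 80 reads to 34 and 42 (adjusted p = 0.0145). USP11 fell by 0.91 (± 0.18, adjusted p = 0.0145) although it stayed far above input. The AKIRIN1 window spans 38990222 to 38992222 on chromosome 1, that of NCF4 36859987 to 36861987 on chromosome 22, and that of DHPS 12680903 to 12682903 on chromosome 19.

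These were among 6 windows past the threshold, 3 higher and 3 lower, with 1808 at an unadjusted p under 0.05. The others had no name: ENSG00000174145 on chromosome 4 rose by 2.43 ± 0.52 and ENSG00000161813 on chromosome 12 fell by 1.52 (± 0.31). Windows named by the lowest p did not pass. On the higher side these were SLC16A10 (2.07 ± 0.48), SERPINB1 (1.92 ± 0.45), LBH (1.95 ± 0.47), PPP1R16B (1.63 ± 0.43), RHEB (1.80 ± 0.48), F13B, DAGLA, CKM and ATP10A. On the lower side they were TOR1B (-1.39 ± 0.33), TNFRSF13C (-1.32 ± 0.32), GDPD4 (-1.53 ± 0.39), EXOC8 (-0.79 ± 0.20), DEFB130A, ZNF554, GHDC, ESS2 and CNKSR1. Without a count filter SLC16A10 (2.08, adjusted p = 0.0366, edgeR), SERPINB1 (1.93, adjusted p = 0.0292) and TOR1B (-1.38, adjusted p = 0.0366) passed. SERPINB1 was at 4.03 without WT OGAP replicate 1. None of the 23 gene lists passed camera, with a smallest adjusted p of 0.176. Adjusted over each list alone, 2 p53 targets (MDM2 at -1.25 ± 0.37 among them), 2 retinal pigment epithelium markers and 1 oxidative phosphorylation gene were lower. DESeq2 called 0 windows, the count was 0 without KD OGAP replicate 1 and 13 without KD OGAP replicate 2, and none of the 4 named calls held without KD OGAP replicate 1 (AKIRIN1 3.21, NCF4 1.47, DHPS -1.16, USP11 -0.94). Further, AKIRIN1 did not pass without WT OGAP replicate 2 (2.93), NCF4 without WT OGAP replicate 1 (1.57), WT OGAP replicate 2 (1.55) or WT input replicate 2 (1.53) or on autosomes without chromosomes 10 and 12 (1.53, adjusted p = 0.0608), DHPS without WT OGAP replicate 1 (-1.46) or 2 (-1.47), and USP11 without WT OGAP replicate 1 (-0.67), KD OGAP replicate 2 (-0.88), with upper quartile scaling (-0.86, adjusted p = 0.0646) or without the mitochondrial windows (-0.91, adjusted p = 0.177, an alternative chosen after seeing the data).

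**Figure D3:**
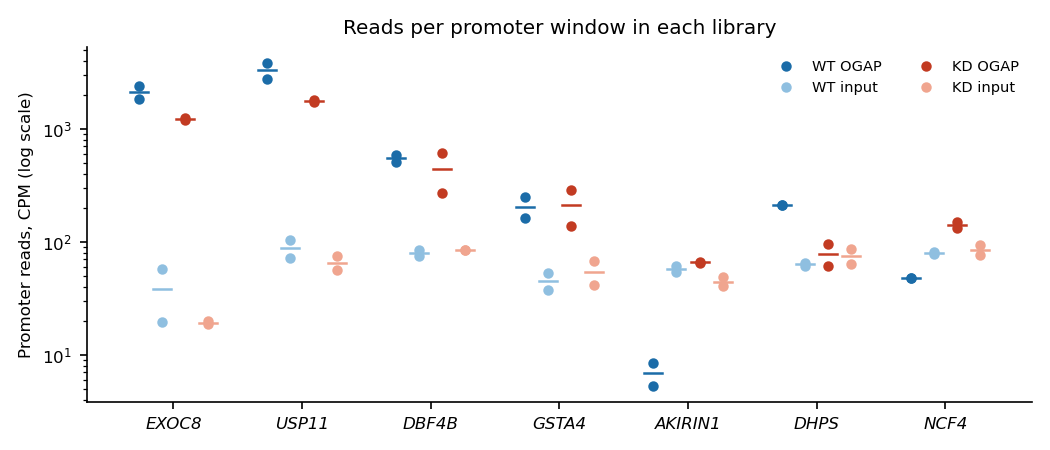
CPM (log scale) in 7 promoter windows; each dot is 1 library and each bar the mean of its group of 2. EXOC8 and USP11 are far above input in both WT OGAP and KD OGAP, whereas AKIRIN1 is lowest in WT OGAP.

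KD against WT in input served as the control for copy number and fragmentation. None of the 17130 windows passed with edgeR, and 756 (4.41%) had an unadjusted p under 0.05, with a smallest adjusted p of 0.999; DESeq2 also called 0, with 212 under 0.05. The windows with the lowest p, none of which passed, were UGT2B10 (2.31 ± 0.57), MSANTD3-TMEFF1 (1.24 ± 0.37), OR5T3, MED18 (1.08 ± 0.33), TYR, ANKRD60, SHISA4, VPS25 and ATP1B4 on the higher side, besides NUMA1. On the lower side they were CMYA5 (-1.33 ± 0.35), GRIK4 (-1.25 ± 0.35), ANKRD36, SREBF1 (-0.98 ± 0.30), PEF1, KCTD5, ASPG, PUS1, RGS11 and TRPM2. By camera, immediate early genes were lower in KD input, with a median of -0.25 over 27 windows of which 6 were positive (adjusted p = 0.0107; adjusted p = 0.473 with an estimated correlation). Olfactory receptors were higher, with a median of 0.13 over 168 windows (adjusted p = 0.0107; adjusted p = 0.634 with an estimated correlation). Neither list had a member past the threshold, and the immediate early list did not pass without WT input replicate 1 (-0.23), WT input replicate 2 (-0.20) or KD input replicate 2 (-0.13). The olfactory list did not pass without WT input replicate 2 (0.08) or KD input replicate 2 (0.03).

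The KD effect on OGAP over input, the interaction, is the comparison closest to the stated purpose. AKIRIN1 was the only window past the threshold, with OGAP over input higher in KD by 3.60 ± 0.71 (adjusted p = 0.0303, edgeR): it was -3.03 ± 0.58 in WT and 0.57 ± 0.38 in KD, and its input held 40 and 47 reads in WT and 28 and 32 in KD. Immediate early genes as a list were higher in the interaction, with a median of 0.60 over 27 windows, 20 of them positive and 0 past the threshold (camera, adjusted p = 0.0125; adjusted p = 0.41 with an estimated correlation). Members with the lowest p were JUND (1.34 ± 0.52), SRF (1.06 ± 0.51), NR4A3 (1.14 ± 0.57) and ZFP36 (0.92 ± 0.46). Part of the list's value comes from its lower reads in KD input, given with the input comparison.

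Other windows in the interaction did not pass, while 1395 (8.14%) had an unadjusted p under 0.05. On the higher side the lowest p belonged to SERPINB1 (2.35 ± 0.57, adjusted p = 0.26, edgeR), ATP10A (2.08 ± 0.52), the creatine kinase gene CKM (1.88 ± 0.48), BMF (1.97 ± 0.52), CAPRIN2, ZNF644, SIX5 (1.96 ± 0.54), CLEC5A, CNNM4 (1.93 ± 0.54) and HEYL. On the lower side it belonged to DHPS (-1.71 ± 0.42), MED18 (-1.74 ± 0.44), LIPF (-2.22 ± 0.57), ZNF99, ZC3H8, ASB11, DHX37, ALDH9A1, SPANXA2 and TRPM6. With at least 50 reads on average DHPS passed (-1.66, adjusted p = 0.049, edgeR). Some values hung on 1 library: without WT OGAP replicate 1, SERPINB1 was at 4.45, CAPRIN2 at 3.89 and ZNF644 at 4.85. Repair genes did not pass, with NEIL1 at -0.92 ± 0.46 and OGG1 at -0.74 ± 0.43, and neither did base excision repair as a list (median -0.48, adjusted p = 0.602). Spindle and NuMA partner genes had a median of 0.25 (adjusted p = 0.602), and oxidative phosphorylation genes -0.20 (adjusted p = 0.567). AKIRIN1 did not pass with DESeq2 (adjusted p = 0.675), with the replicate block nested in genotype (3.61, adjusted p = 0.165) or without any of WT OGAP replicate 2 (3.30), WT input replicate 2 (3.48), KD OGAP replicate 1 (3.59), KD OGAP replicate 2 (3.62), KD input replicate 1 (3.47) and KD input replicate 2 (3.74); the list did not pass without WT OGAP replicate 2 (0.52), WT input replicate 1 (0.51), KD OGAP replicate 2 (0.56) or KD input replicate 2 (0.49).

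**Figure D4:**
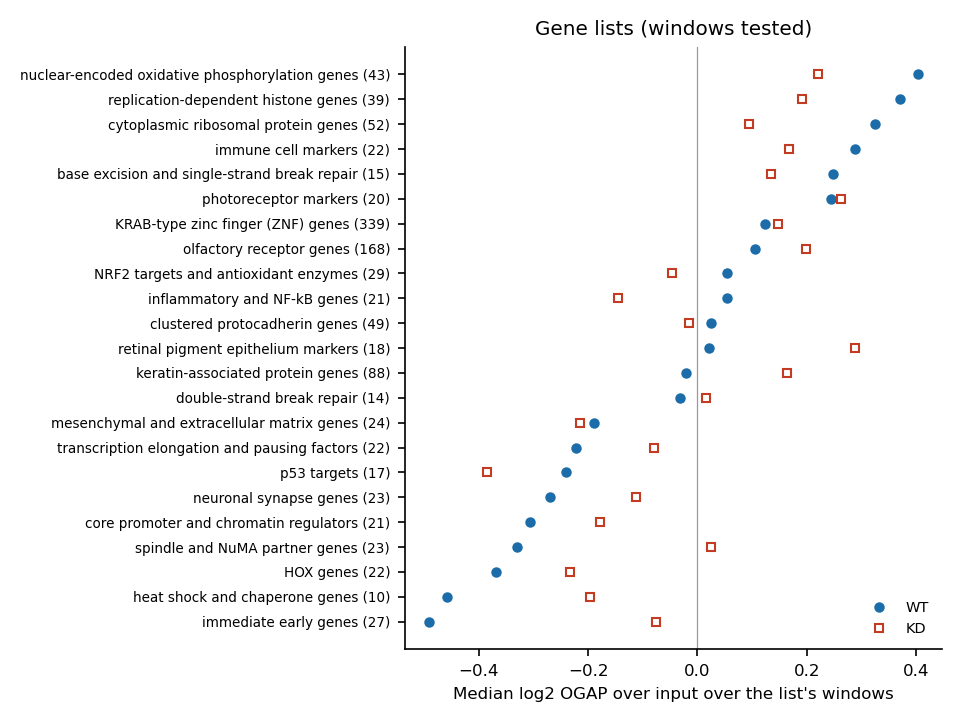
Median log2 OGAP over input over the windows of each of the 23 gene lists in WT (filled circles) and KD (open squares); the number of windows tested is in parentheses. Immediate early genes were lowest in WT at -0.49 and nearer 0 in KD at -0.08.

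Reads in OGAP and input were also compared by chromosome. Chromosome 19 took 8.68% ± 0.54 of promoter reads in the 4 OGAP libraries and 7.73% ± 0.14 in the 4 inputs, with 9.14% in WT OGAP and 8.21% in KD OGAP. The 13 mitochondrial windows took 2.20% ± 0.13 of OGAP reads and 2.81% ± 0.22 of input reads. All OGAP libraries lay on the same side of all inputs for both (exact permutation p = 0.0286 each, two-sided, the smallest possible; adjusted p = 0.0762 over 24 chromosomes, so neither passed). Chromosomes 1, 7 and 12 were also higher and chromosomes 2, 10, 13 and 20 lower in every OGAP library than in every input.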

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

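The tests on input libraries by OGAP alone, read totals, uniform admixture and a change of damage in the paragraph on the genome-wide difference, the test of the immediate early list in OGAP alone, and both tests of the 3 windows with the lowest p were chosen only after the result was seen. The tests by thinning (the slope and the number of calls), by exchanged inputs, by the difference between inputs and by matched lists were set before their result was seen. Some tests followed earlier ones: OGAP alone was examined after exchanged inputs had not decided, and was divided into high and low windows after both together had not decided either; the number of calls was examined because thinning had not moved the slope; a bound over pairs of libraries was added for the immediate early list; and at the 3 windows a test of input reads that had not decided was replaced by ratios of OGAP to input, then limited to KD because WT had served to choose the windows.

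AKIRIN1 differed between WT and KD in OGAP over input by a log2 value of 3.60 in the interaction test. WT OGAP held 3 and 2 reads there and each other library between 28 and 47. Its call rested on most of the libraries, as given with the comparison, and no explanation was tested for this single window.

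Immediate early genes differed between WT and KD in OGAP over input by a median of 0.602 in the interaction test of the list (camera, adjusted p = 0.0125; adjusted p = 0.41 with an estimated correlation). Among 10000 lists matched on WT OGAP over input, the median lay at the 94.98th percentile, inside the central 95% that was set as the bound beforehand, and such lists had a median of 0.42. The matching used measured WT values, which the interaction subtracts. Noise in these values therefore raises the median of the matched lists and lowers the percentile of the immediate early list. The test thus does not decide how much of the list's value the genome-wide difference described next explains, and that difference stays a possible explanation. Differing inputs stay open as well. In OGAP alone the list's median of 0.292 lay at the 99.75th percentile of lists matched on mean log2 CPM, but at the 96.25th in the lowest pair of libraries, under the bound, and camera did not pass there (adjusted p = 0.24). In input alone the median was -0.246, at the 0.2nd percentile. An effect of NuMA depletion on these promoters stays open and untested beyond this.

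Differences between promoters in log2 OGAP over input were smaller in KD than in WT. The SD across windows that replicates shared was 0.332 in KD and 0.621 in WT. The typical level cannot be compared, because scaling centres it (median log2 of -0.022 in WT and 0.032 in KD). Across 8594 windows the noise-corrected slope of KD on WT was 0.539 (0.408 to 0.677 over pairs of libraries), with a noise-corrected correlation of 1.01. Thinning all libraries to one total gave a slope of 0.537, which decides nothing because the noise correction leaves depth little to change. Nor do 10 thinnings decide on the fewer calls in KD (at most 3.2% as many as in WT), because the KD pull-downs were the deeper ones and lost more reads. Fewer reads in the KD pull-downs are argued against by their totals, the lower of which was 1.13 times the higher WT total. Exchanging the inputs of WT and KD gave a slope of 0.665 (0.486 to 0.846 over pairs), which does not decide over all windows because the highest pair passed 0.8. Differing inputs as the whole cause are argued against for windows high in WT OGAP by OGAP alone, where KD lay below WT by a log2 value of -0.418 (-0.504 to -0.332 over pairs); for windows low in WT OGAP the value was 0.219 (0.090 to 0.347), which leaves inputs open there because the lowest pair was under 0.1. A uniform admixture of input-like fragments in the KD pull-down would need the same share in every class. The shares were -33.3% for mitochondrial windows (-65.9 to -4.3 over pairs) and 65.9% for chromosome 19 (59.2 to 72.4). They were 48.8% for windows high in WT OGAP (40.3 to 57.2), 33.4% for windows low in it (14.3 to 51.1) and 35.9% for gene starts (22.5 to 48.6). The range for mitochondrial windows is wide but overlaps no other. These windows alone do not decide, because their share of reads differed between the WT inputs themselves. They may also overlap one another, where shared reads seem to have been left uncounted. Among the nuclear classes the range for chromosome 19 overlapped no other either. Its lowest pair, at 59.2%, lay only just above the highest pair of windows high in WT OGAP, at 57.2%. One uniform share is therefore argued against only weakly. Still open is an admixture, at least as part of the cause. A library bias that also varies between inputs is open too, since the difference between the WT inputs correlated with WT OGAP over KD input at r = -0.16 across windows (0.07 for the KD inputs). So is a change of damage on NuMA depletion, with the highest slope over pairs at 0.677. With 2 libraries per group and doxycycline in KD alone these cannot be told apart.

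USP11, EXOC8 and DBF4B, the 3 windows with the lowest p for OGAP over input in WT, were high in both states. Extra genomic copies or collapsed repeats would raise input as well, but in KD, which had no part in choosing the windows, the lower OGAP library held at least 3.11 times the CPM of the higher input at each of the 3. The earlier test had been undecided, because USP11 reached the 97.9th percentile of windows in WT input replicate 1, against a bound at 95. Amplified fragments in 1 library are argued against by the lower KD OGAP library, at 3.12 times the mean KD input or more. Fragments that the pull-down binds for another reason than damage were not tested, and no biological explanation was tested.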

How the results depend on the processing

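Of the alternative values, 143 that answer a comparison and 2494 others kept their direction and side of the threshold, or their size. Of the first kind 33 were weaker, 10 stronger and 9 moved, and of the others 57, 18 and 1. The direction reversed in 52 more, none of them past the threshold, as given last. GC correction, alone or with the replicate block, was not run because no genome sequence was used here. The cause was not tested for the changes that follow, except that the 50-read filter tests only 679 windows and a left-out library leaves its group with 1, assumed to vary like the rest. The DESeq2 test called 884 windows for OGAP over input in WT, 64 in KD, 0 for KD against WT in OGAP and 0 for the interaction; in KD it left 15941 adjusted p-values missing. With at least 50 reads on average these were 257 in WT, 73 in KD and 2 for the interaction. Without a filter KD against WT in OGAP had 12 calls and the interaction 3; the interaction also had 3 with DESeq2 size factors. Autosomes without chromosomes 10 and 12 gave 60 in KD and 2 for KD against WT in OGAP. Windows that overlap no other, chosen after seeing the data, gave 3 for the interaction. In total-count scaling the WT split was 1370 higher and 993 lower. Lists past the threshold were 0 with an estimated correlation in WT, input and the interaction, and with fry 7 in WT and 0 in input. In the interaction fry called 1 list, as camera did, the immediate early genes (fry, adjusted p = 0.0204). Lists that passed in WT with fry but not with camera were ribosomal protein (fry, adjusted p = 0.0233), ZNF (0.025), double-strand break repair (0.0263) and immune marker genes (0.0397), all higher. Neuronal synapse genes (0.0475) were lower.

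Replicate numbers did not pair the libraries: correlations of replicate differences between groups ran from -0.04 to 0.024. With the replicate block 2181 windows were called in WT, 97 in KD, 5 for KD against WT in OGAP, 0 in input and 1 for the interaction; nested in genotype, the block gave 0 for the interaction.

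Leaving out each library gave 879 to 2455 calls in WT, 7 to 163 in KD, 0 to 13 for KD against WT in OGAP, 0 to 0 in input and 0 to 6 for the interaction, where the 6 came without WT OGAP replicate 1. Without WT input replicate 2, and without KD input replicate 1, the 1 call of the interaction was not AKIRIN1 but a window that was lower. Lists ran from 1 to 3 in WT, 0 to 2 in KD, 0 to 2 in input and 0 to 1 for the interaction. KD minus WT in OGAP coverage ran from 0.082 to 0.156 at gene starts, 0.051 to 0.084 at gene ends and 0.077 to 0.150 over exons. Settings chosen after seeing the data moved some values: the central mean as deposited gave differences of 0.217, 0.192 and 0.211, and windows in the upper part by mean count gave replicate correlations of 0.474 in WT input, 0.326 in KD OGAP and 0.347 in KD input. KD OGAP replicates correlated at 0.496 over windows without overlap, and KD input at 0.586, with a Spearman value of 0.609. The slope of KD on WT was 0.665 with inputs exchanged. At this depth and with 2 libraries per group, 23.9% of simulated 2-fold changes were recovered in WT, 28.4% for KD against WT in OGAP and 6.0% for the interaction. These changes were simulated only in windows at or above the median abundance. Each simulation held 200 changed windows, unlike the data, so the shares are not recovery rates of these data.

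The reversed values concern windows and list medians that had not passed. OGAP over input in KD at CNNM4 was -0.02 with DESeq2 size factors, in the 4-library fit with or without a replicate block, and over windows without overlap. It was -0.03 with total counts, with upper quartile scaling and on autosomes without chromosomes 10 and 12, and -0.01 without a filter. DHPS in KD was 0.0 with total counts (negative before rounding), and -0.01 with upper quartile scaling and on those autosomes. NUMA1 between KD and WT in OGAP was 0.02 with total counts and 0.03 with upper quartile scaling. In WT, total counts gave list medians of -0.018 for NRF2 targets, -0.051 for protocadherins, -0.021 for inflammatory genes and -0.052 for retinal pigment epithelium markers. Fry gave a direction opposite to camera for p53 targets (median -0.24) and inflammatory genes (0.054).

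With each library left out, KD values ran from -0.31 to 0.42 at CNNM4, -0.29 to 0.33 at DHPS, -0.58 to 0.48 at MYH9, -1.2 to 0.14 at TMEM200B and -0.98 to 0.35 at NUMA1. NUMA1 in OGAP ran from -0.73 to 0.39 and NCF4 in input from -0.07 to 0.23. List medians in WT ran from -0.488 to 0.122 for p53 targets, -0.105 to 0.084 for inflammatory genes, -0.090 to 0.607 for base excision repair, -0.070 to 0.175 for double-strand break repair, -0.151 to 0.025 for protocadherins, -0.088 to 0.160 for keratin-associated proteins and -0.017 to 0.254 for retinal pigment epithelium markers. For core promoter regulators (-0.425 to -0.023) and elongation factors (-0.300 to -0.011) only the direction of the camera test changed. Immediate early genes in KD ran from -0.179 to 0.058. Of 1092 alternative values for lists whose medians are not reported, 130 reversed and 0 of these passed.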

Other observations

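Mitochondrial windows went against the nuclear pattern: their share of OGAP reads was 2.28% in WT and 2.12% in KD, while their share of input reads was 2.70% and 2.92%, so that KD was not closer to its input. Per library the shares were 2.23% and 2.34% in WT OGAP, 2.20% and 2.03% in KD OGAP, 2.90% and 2.5% in WT input, and 2.84% and 3.0% in KD input. The difference in share between WT and KD was not tested. It was not particular to mitochondrial windows that KD came no closer to its input. Chromosome 1 took 10.43% of WT OGAP and 10.24% of WT input reads, and 10.52% and 10.26% in KD. Other chromosomes, such as chromosome 19, did come closer in KD.

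Libraries of the same state were unlike each other in the size of OGAP over input. The slope of KD on WT was 0.466 with KD replicate 1 and 0.611 with KD replicate 2, and it was 0.477 with WT replicate 1 and 0.601 with WT replicate 2. The coverage ratio at gene starts was 1.01 and 0.933 in KD OGAP. At DBF4B the KD OGAP libraries held 151 and 270 reads.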
